A study of Mus musculus with 15 samples.

How the data were processed

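Right hippocampi of 15 male C57BL/6 mouse pups, 3 in each of 5 groups, were profiled by the submitters on Affymetrix Mouse Gene 1.0 ST arrays, single-colour arrays with probes along the exons of each gene. The values are log2 intensities that the authors deposited in a table of the whole series with a column per array. They were made with RMA, which corrects the background, quantile-normalizes the arrays and summarises probes, per the submitters' processing notes, and its software and version are not given in the sources used here. The table was used as deposited, with no further transformation before the main tests. Array medians differed by up to 0.19, and quantile normalization and median centring, fixed beforehand as alternatives, show what scaling changes. Median centring moves every gene of a comparison by the same amount, so it can add a shift as well as remove it. All 15 columns matched a sample, and 0 columns were left unused.

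The table has 35557 probe sets. The platform annotation given for them lists 23410, of which 21789 carry 1 gene symbol and 1621 several, and 12147 are unnamed here. Only probe sets with 1 symbol were used for genes, and where a gene had several the brightest over all 15 arrays was kept, which left 19938 genes. Of these, 19919 symbols were found in the RefSeq gene table of assembly GRCm38.p6, which served only for names and for the length of genes, and 4 members of the gene lists were matched through older symbols. No filter on dim genes was applied before the tests.

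Groups were taken from the treatment given for each sample. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group on all 15 arrays, then eBayes). The 5 groups then share an estimate of the spread with 10 residual degrees of freedom, against 4 for a pair of groups alone, to which eBayes added 4.61 prior degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over the 19938 genes of a comparison and a threshold of 0.05. The 11 contrasts were the 4 treated groups against CC, MSM against MSS, SSM against SSS, SSS against MSS, SSM against MSM, the mean of both morphine differences, the mean of both severity differences and the interaction of morphine with severity, and an F-test covered all 5 groups. The titles also hold an SS number of unstated meaning, 12 for CC, 11 for mild stress and 8 to 10 for severe stress. It is nested in the stress level and was therefore left out of the model and tried as a block.

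Before the data were examined, 30 gene lists (541 members, 488 measured, 6 to 23 per list) and the rule for naming genes were fixed. The lists were glucocorticoid response, corticotropin and steroid receptor genes, hypoxia response, immediate early genes, opioid peptides, receptors and signalling, myelin and mature oligodendrocyte, oligodendrocyte precursor, astrocyte, microglia, endothelial and pericyte, glutamatergic neuron, interneuron, glutamate and GABA receptors and chloride transporters, cell cycle, and neurogenesis and immature neuron. Further lists were cholesterol synthesis, fatty acid oxidation and ketone use, unfolded protein and amino acid response, heat shock, inflammation and acute phase, interferon response, apoptosis, circadian clock, synapse and vesicle release, dopamine, serotonin, noradrenaline and acetylcholine genes, choroid plexus, thalamus, meninges and fibroblast, ependyma and cilia, and blood. Each was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 30 lists of a comparison, again with the correlation estimated from the data, and with fry. Members were also counted as past the threshold over all genes and adjusted over the list alone. Named were, for each comparison, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap (a condition not set for averaged contrasts and the interaction), or, where fewer than 10 passed, the 5 rises and 5 falls with the smallest p-values as values. Of each list up to 4 members were named by smallest p. Predicted genes, RIKEN clones, olfactory and vomeronasal receptors, microRNAs and other small RNAs were counted and passed over for naming, except where the text says so. A striatum list (16 measured) and a list of RNAs known to be retained in the nucleus (14 measured) were added after the data were seen, and their p-values were adjusted over these 2 lists. So were 9 further thalamus genes, of which only means per array were used.

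The fits were tested on simulated data for SSM against CC (19938 genes, 10 simulations). Each simulation held 200 changed genes, divided evenly over the folds that follow. Recovered were 38.8% of genes changed 1.25-fold, 92.8% of those changed 1.5-fold, 99% at 2-fold and 100% at 3-fold. False calls averaged 10 per simulation. A list shifted by 0.3 was called in 10 of 10 simulations with the preset and with the estimated correlation. No unchanged list was called. The simulated genes were independent of one another, so these rates do not carry over to lists whose genes move together. Correlations of comparisons that share arrays were set beside 100 simulations of unchanged groups. Alternatives planned beforehand were a fit of the compared groups alone, a variance prior with trend and robust estimation, dropping the 40% dimmest genes, every probe set in place of a gene's brightest, and quantile normalization once more. Others were median centring, array weights, the SS number as a random or fixed block, the H number of the titles as a replicate block, leaving out each array, and for lists the estimated correlation, fry and the mean over a gene's probe sets. Chosen after the data were seen were the fits without SSM replicate 1 and MSM replicate 3, with and without quantile normalization, and the list tests under scaling and left-out arrays.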

Results

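Gene expression was measured in the right hippocampus of male C57BL/6 mouse pups on postnatal day 9, with the day of birth counted as day 1. The pups belonged to 5 groups of 3: untreated controls (CC), mild stress with saline (MSS), mild stress with the opioid morphine (MSM), severe stress with saline (SSS) and severe stress with morphine (SSM). Treatment ran from postnatal day 5 to day 9, and litters held at most 7 pups per dam. What the mild and the severe stress consisted of, and the morphine dose, are not given in the sources used here. Total RNA of each sample was read on an Affymetrix Mouse Gene 1.0 ST array. All values below are log2 intensities (RMA), group values are means ± SD (n = 3 arrays per group), and differences are log2 differences with the standard error (SE) from limma. The litter of each pup is not given in the sources used here, so p-values measure the spread between these arrays only.

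The 15 arrays resembled one another closely, with pairwise correlations across genes from 0.988 to 0.997 and no identical pair. The array medians lay between 5.41 and 5.51 on 14 arrays and at 5.60 on SSM replicate 3, whose genes lay higher than those of the other arrays by a median of 0.16. Eif2s3y, a Y-linked gene, was 7.43 to 8.23 on every array, and Xist, expressed from the inactive X chromosome of females, was 4.01 to 4.44, as the male labels require. Among 19938 genes compared, the number of arrays limited the precision: the median SE of a difference between 2 groups was 0.081.

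Genes of tissue that borders the hippocampus differed sharply between arrays of the same group. Ttr, which codes for the thyroid hormone carrier made by the choroid plexus, was 9.17 and 8.99 in MSS replicates 1 and 2 and 8.87 in SSS replicate 2, against 12.65 to 13.24 in the other 12 arrays. Tcf7l2, a transcription factor of thalamic neurons, reached 9.85 in MSM replicate 3 against 6.01 to 7.53 elsewhere, and 11 of the 13 measured thalamus genes were highest in that array. In SSM replicate 1 the enkephalin precursor Penk was 11.40 and the dopamine receptor gene Drd1 9.72, both abundant in striatum, against at most 10.08 and 7.97 elsewhere, both in CC replicate 1. The myelin genes Mbp (9.40 and 9.24) and Mag (8.45 and 8.19) were highest in these same arrays, SSM replicate 1 and MSM replicate 3. Ttr, Tcf7l2, Penk, Drd1, Mbp and Mag were chosen for this paragraph after their values were seen. Every comparison was therefore also computed without SSM replicate 1 and MSM replicate 3.

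**Figure D1:**
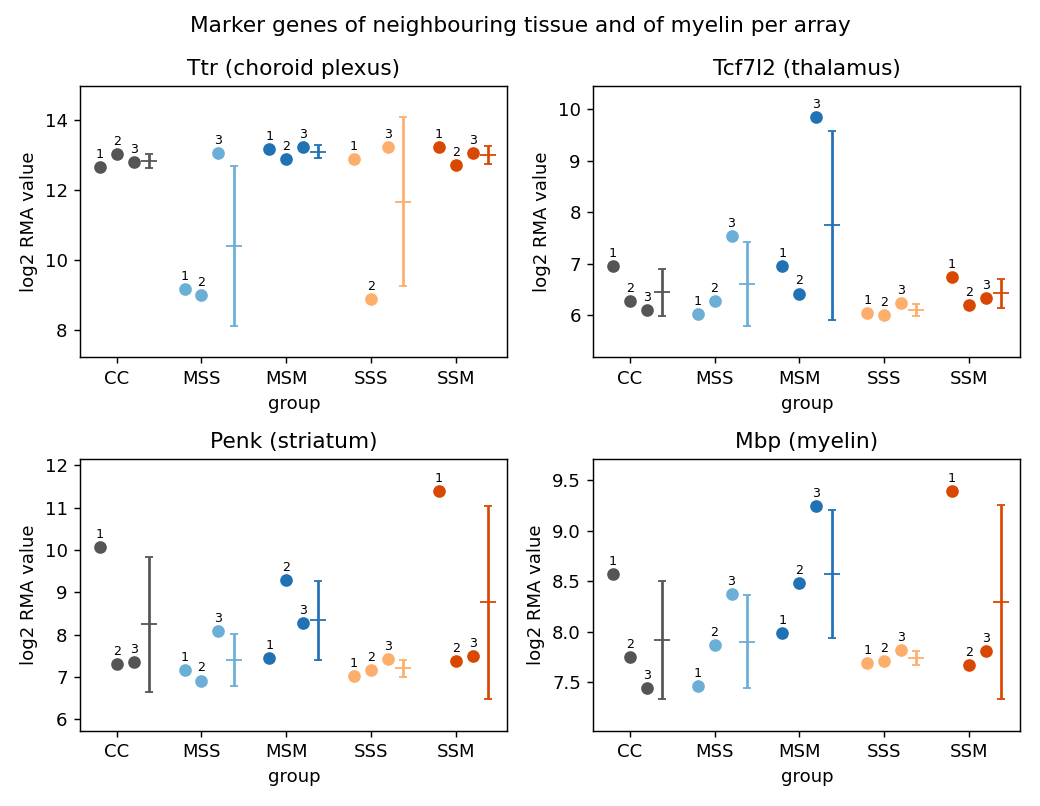
Log2 intensity (vertical axes) of Ttr, Tcf7l2, Penk and Mbp by group (horizontal axes), with a point for each array and a bar for the group mean ± SD (n = 3). Ttr sits near 9 in 3 arrays (9.17, 8.99 and 8.87), Tcf7l2 reaches 9.85 in MSM replicate 3, and Penk reaches 11.40 in SSM replicate 1.

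The 30 gene lists fixed beforehand were tested in 11 comparisons with camera, which compares the genes of a list with all other genes. With the preset correlation between genes, 54 of the 330 tests were called, 20 toward higher and 34 toward lower expression. None of the 54 calls held with an estimated correlation (0 calls, smallest adjusted p = 0.493). The fry test, which asks whether a list moves on balance in a given direction without comparing it with other genes, called 0 (smallest adjusted p = 0.115). Its mixed form, which allows both directions, called 5: the circadian clock list in SSM against CC, SSM against SSS and both averaged contrasts, and the unfolded protein and amino acid response in the severity contrast. Leaving out each array in turn kept 14 of the 54 camera calls in every fit and ended 40, and 32 were kept without SSM replicate 1 and MSM replicate 3. In the comparisons that involve SSM the median over all genes was shifted upward, by 0.062 against CC, 0.056 against SSS and 0.063 against MSM, and camera's direction is relative to that shift. Without SSM replicate 3 the shift was 0.0077, 0.00098 and 0.0074.

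**Figure D2:**
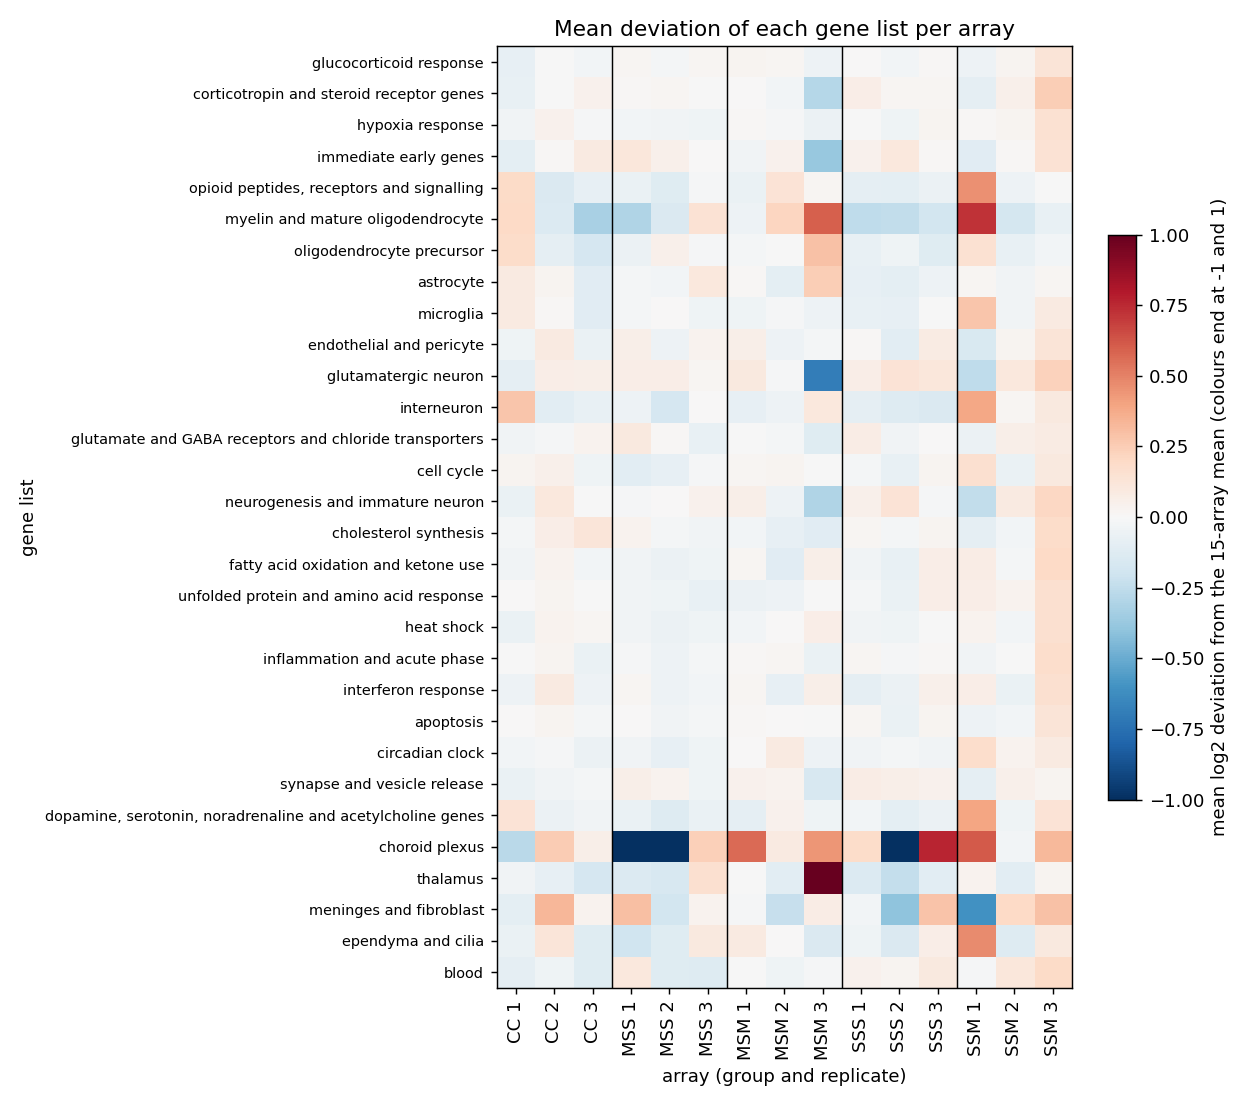
Heat map of the 30 gene lists (vertical axis) on the 15 arrays (horizontal axis, ordered by group), coloured by the mean log2 deviation of the list's genes from their means over all arrays. The thalamus list stands at 1.05 in MSM replicate 3 and at no more than 0.16 in the other 14 arrays.

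Severe stress was set against mild stress by averaging the difference over saline and morphine. Kbtbd7, which codes for a substrate adaptor of a cullin ubiquitin ligase, rose by 0.26 (SE 0.037, adjusted p = 0.0467), from 7.50 ± 0.015 in MSS and 7.39 ± 0.041 in MSM to 7.67 ± 0.027 in SSS and 7.74 ± 0.059 in SSM (n = 3 each). It was 7.67 ± 0.045 in CC. Mir380, a microRNA gene of the imprinted Dlk1 to Dio3 cluster, fell by 0.88 (SE 0.10, adjusted p = 0.00597), from 5.58 ± 0.23 and 5.48 ± 0.089 under mild stress to 4.73 ± 0.21 and 4.56 ± 0.15 under severe stress. In CC it was 5.05 ± 0.26. In both genes all 6 severe-stress arrays lay beyond all 6 mild-stress arrays, and Mir380, which lies outside the naming rule, was chosen after its values were seen. The genes with the next smallest p-values did not pass. Among those with the higher means were Rnpep 0.34 (SE 0.057), Pfn1 0.30 (SE 0.050) and Banf1 0.24 (SE 0.041), which code for an aminopeptidase, the actin-binding profilin and a chromatin-binding protein (adjusted p = 0.0630 each). Dbp 0.36 (SE 0.065), a clock-controlled transcription factor, followed (adjusted p = 0.0820). Among those with the lower means were Clk1 -0.59 (SE 0.10), a kinase of splicing factors, the splicing regulator Arglu1 -0.35 (SE 0.061), the nuclear kinase anchor Akap8 -0.33 (SE 0.057), Eml5 -0.44 (SE 0.074) and Ankrd16 -0.29 (SE 0.048) (adjusted p = 0.0630 each). Clk1 was 9.63 ± 0.055 in MSS, 9.65 ± 0.17 in MSM, 9.02 ± 0.35 in SSS and 9.07 ± 0.12 in SSM.

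**Figure D3:**
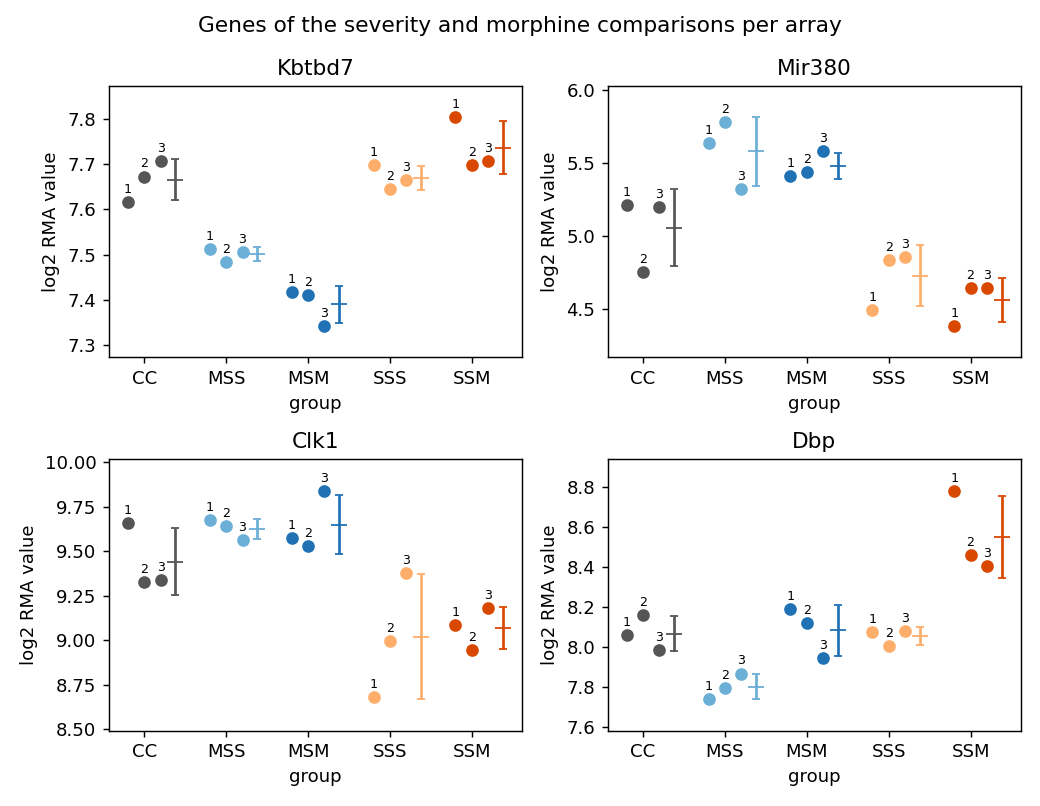
Log2 intensity (vertical axes) of Kbtbd7, Mir380, Clk1 and Dbp by group (horizontal axes), with a point for each array and a bar for the group mean ± SD (n = 3). The Mir380 means are 5.58 in MSS and 5.48 in MSM, and 4.73 in SSS and 4.56 in SSM, and the highest Dbp mean is 8.55 in SSM.

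Across the severity contrast 2 of 19938 genes passed (1 higher, 1 lower), and 2410 had an unadjusted p under 0.05, 1851 of them higher, where chance alone gives 997. After centring each array on its median 4322 of 4674 such genes were higher, after quantile normalization 1824 of 2637, and without SSM replicate 3 1194 of 2127. Centring moved every gene of this contrast upward by the same amount (Kbtbd7 from 0.257 to 0.287). It thus added to the median over all genes, 0.035 before centring, so its count is no check on that shift. Of the genes of the unfolded protein and amino acid response, 19 of 22 were higher under severe stress (median 0.089, camera adjusted p = 0.0133). Among them were the proline synthesis gene Aldh18a1 0.16 (SE 0.041), the endoplasmic reticulum chaperone Dnajb9 0.23 (SE 0.070), the serine synthesis gene Phgdh 0.22 (SE 0.070) and Chac1 0.19 (SE 0.065). Astrocyte genes were lower in 10 of 14 (median -0.086, adjusted p = 0.0105; Gfap -0.20 (SE 0.11) and Aqp4 -0.19 (SE 0.10)). Oligodendrocyte precursor genes were lower in 9 of 14 (median -0.086, adjusted p = 0.0105; Pcdh15 -0.25 (SE 0.086)). Myelin genes were lower in 12 of 17 (median -0.066, adjusted p = 0.0133). Thalamus genes were lower in 12 of 13 (median -0.17, adjusted p = 2.38e-04), with Tcf7l2 at -0.91 (SE 0.45), and MSM replicate 3, the array with the high thalamus markers, is on the mild-stress side. Camera with an estimated correlation gave an adjusted p of 0.856 for each of these 5 lists. Adjusted over the list alone 1 of 22 unfolded protein genes passed and 0 in the other 4 lists, and over all genes 0 passed in any of them. A gene also passed over its list alone in each of 5 uncalled lists: opioid, glutamatergic neuron, cell cycle, neurogenesis and circadian clock. With the SS number of the titles as a random block Mir380 alone passed in limma (adjusted p = 0.0248) and Kbtbd7 did not (adjusted p = 0.163). That fit used the same correlation within SS numbers for all genes (0.0650). All mild-stress arrays share an SS number that no severe-stress array has, so it cannot tell the stress level from the SS number. Without SSM replicate 1 and MSM replicate 3 Mir380 passed (adjusted p = 0.0234) and Kbtbd7 did not (adjusted p = 0.112), and with quantile normalization in addition neither did (adjusted p = 0.0566 and 0.0764). Kbtbd7 passed in 2 of the 15 fits that left out an array, those without SSS replicate 3 (adjusted p = 0.0389) and SSM replicate 3 (adjusted p = 0.0254). With arrays left out, the myelin call ended without MSS replicate 3, MSM replicate 3, SSM replicate 2 or SSM replicate 3 (adjusted p = 0.130, 0.440, 0.101 and 0.457, median -0.0029, -0.033, -0.028 and -0.065). The oligodendrocyte precursor call ended without MSM replicate 3 or SSM replicate 3 (adjusted p = 0.362 and 0.282, median -0.0089 and -0.067). The astrocyte call ended without MSM replicate 3 or SSM replicate 3 (adjusted p = 0.238 and 0.239, median -0.028 and -0.076). The unfolded protein call ended without MSM replicate 1, SSS replicate 3 or SSM replicate 1 (adjusted p = 0.0505, 0.0877 and 0.105, median 0.10, 0.079 and 0.091). The thalamus call ended without MSM replicate 3 (adjusted p = 0.233, median -0.057). All 5 calls held with SSM replicate 1 and MSM replicate 3 both left out (adjusted p up to 0.0297). The medians were then -0.097 for myelin (adjusted p = 5.86e-05), -0.044 for oligodendrocyte precursor, -0.036 for astrocyte, -0.068 for thalamus and 0.103 for unfolded protein. Quantile normalization in addition kept the myelin, oligodendrocyte precursor and astrocyte calls. It ended those of unfolded protein and thalamus (adjusted p = 0.101 each).

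Within the saline groups, severe stress was compared with mild stress through SSS and MSS. Choroid plexus genes were higher in SSS in 15 of 15 (median 0.51, camera adjusted p = 2.06e-05), among them the tight junction gene Cldn2 0.57 (SE 0.28) and the water channel gene Aqp1 0.90 (SE 0.45). Astrocyte genes were lower in 11 of 14 (median -0.11, adjusted p = 0.0138), with the gap junction genes Gja1 -0.18 (SE 0.085) and Gjb6 -0.30 (SE 0.16). Once the correlation was estimated the adjusted p was 0.852 for both lists, and adjusted over the list alone, as over all genes, 0 of their genes passed. The uncalled circadian clock list had 1 of 15. Ttr was below 9.2 in 2 of the 3 MSS arrays and 1 of the 3 SSS arrays. In limma no gene passed (0 of 19938, smallest adjusted p = 0.527), and 568 had an unadjusted p under 0.05, 255 of them higher (596 of 941 after quantile normalization, 1018 of 1179 after median centring). The smallest p-values belonged to Banf1 0.24 (SE 0.058), Tex264 0.30 (SE 0.073), Zbtb2 0.29 (SE 0.074), Sh3glb1 0.20 (SE 0.055) and Sdhaf1 0.20 (SE 0.055) on the higher side. On the lower side they belonged to Tbrg3 -0.47 (SE 0.089), Tmem267 -0.93 (SE 0.19), Efcc1 -0.32 (SE 0.069) and Eml5 -0.45 (SE 0.11) and the co-chaperone gene Dnajb6 -0.53 (SE 0.11). The astrocyte call ended without MSS replicate 3 (adjusted p = 0.158, median -0.052) and the choroid plexus call without SSS replicate 3 (adjusted p = 0.619, median 0.11).

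Under morphine, severe stress was compared with mild stress through SSM and MSM. In the main fit this comparison had the most genes at an unadjusted p under 0.05. Kbtbd7 0.35 (SE 0.052) and the homeobox gene Pknox1 0.45 (SE 0.069) came nearest to the threshold (adjusted p = 0.0764 each). Rnpep 0.49 (SE 0.080) (adjusted p = 0.116) came next, before Sap30bp 0.35 (SE 0.063) and the synaptotagmin gene Syt5 0.48 (SE 0.087) (adjusted p = 0.156 each). On the lower side stood Sfi1 -0.49 (SE 0.089), Thoc2l -0.33 (SE 0.068), Akap8 -0.39 (SE 0.081) and Krtap5-3 -0.48 (SE 0.10) and the Mediator subunit gene Med12 -0.41 (SE 0.089) (adjusted p = 0.156 each). Thalamus genes were lower in SSM in 12 of 13 (median -0.22, camera adjusted p = 8.09e-05; Lef1 -0.62 (SE 0.28) and Tcf7l2 -1.32 (SE 0.63)). Oligodendrocyte precursor genes were lower in 10 of 14 (median -0.076, adjusted p = 0.0279; Pcdh15 -0.32 (SE 0.12)). With an estimated correlation the adjusted p was 0.917 for both lists. Over the list alone 4 of 15 microglia genes passed, among them Fcer1g 0.31 (SE 0.083) and C1qb 0.34 (SE 0.10). So did 2 of 16 interneuron genes, Sst 0.41 (SE 0.10) and Htr3a 0.52 (SE 0.14). A single gene passed in each of the opioid (Npff -0.40 (SE 0.091)), hypoxia (Vegfa -0.30 (SE 0.081)), glutamatergic neuron (Calb1 0.61 (SE 0.13)), cell cycle (Mcm2 0.30 (SE 0.073)) and circadian clock lists (Dbp 0.46 (SE 0.091)). None of these passed over all genes, and camera did not call those lists. These counts include SSM replicate 1, where most microglia genes peaked, and SSM replicate 3, whose genes lay higher by a median of 0.16. Of 19938 genes 0 passed in limma and 2858 had an unadjusted p under 0.05, 2408 of them higher (1796 of 2645 after quantile normalization, 1123 of 1992 without SSM replicate 3). MSM replicate 3 carried the high thalamus markers. The thalamus call ended without MSM replicate 3 (adjusted p = 0.626, median 0.042), and the oligodendrocyte precursor call without MSM replicate 3 or SSM replicate 3 (adjusted p = 0.644 and 0.627, median 0.036 and -0.036). Without MSM replicate 3 both medians were above 0, while camera's direction, relative to the other genes, stayed lower. With SSM replicate 1 left out in addition the oligodendrocyte precursor call held (median -0.024, adjusted p = 0.0271). It ended once quantile normalization was added to that fit (adjusted p = 0.117).

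Morphine was set against saline by averaging the difference over mild and severe stress. Dbp was higher with morphine by 0.39 (SE 0.065) (adjusted p = 0.548), at 8.08 ± 0.13 in MSM against 7.80 ± 0.063 in MSS and 8.55 ± 0.20 in SSM against 8.05 ± 0.043 in SSS. Every morphine array lay above every saline array of its stress level. The circadian clock list was called higher (13 of 15, median 0.080, camera adjusted p = 0.00875), with the clock repressor genes Cry1 0.32 (SE 0.10), Nr1d2 0.16 (SE 0.059) and Bhlhe41 0.16 (SE 0.062) next to Dbp. Choroid plexus genes were higher in 15 of 15 (median 0.51, adjusted p = 1.13e-06; Ttr 2.02 (SE 0.72), Clic6 1.31 (SE 0.49), Kcne2 0.46 (SE 0.16) and Steap1 0.24 (SE 0.074)). Myelin genes were higher in 16 of 17 (median 0.32, adjusted p = 2.07e-05; Trf 0.32 (SE 0.091) and Tspan2 0.41 (SE 0.12)). Cell cycle genes were higher in 19 of 20 (median 0.066, adjusted p = 0.00875, the mitotic kinase gene Aurkb 0.18 (SE 0.063) and Pcna 0.11 (SE 0.043)). Immediate early genes were lower with morphine in 14 of 18 (median -0.096, adjusted p = 1.13e-06; Dusp6 -0.22 (SE 0.092) and Junb -0.11 (SE 0.052)). Glutamatergic neuron genes were lower in 11 of 14 (median -0.21, adjusted p = 8.26e-06; Neurod2 -0.23 (SE 0.11) and Prox1 -0.35 (SE 0.18)). Synapse and vesicle release genes were lower in 15 of 18 (median -0.062, adjusted p = 3.12e-05; the scaffold gene Shank1 -0.19 (SE 0.074)). Also called lower were neurogenesis and immature neuron (13 of 17, median -0.063, adjusted p = 0.00188), cholesterol synthesis (12 of 16, median -0.035, adjusted p = 0.00277) and glutamate and GABA receptors (12 of 21, median -0.031, adjusted p = 0.0420). With an estimated correlation the adjusted p of these 10 lists was 0.493 to 0.692. Adjusted over the list alone 2 of 17 myelin genes and 1 of 15 clock genes passed, with 0 in the other 8 called lists and 0 over all genes. Of the uncalled lists, interneuron and unfolded protein genes had 1 each.

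No gene passed in limma in the averaged morphine contrast (0 of 19938), and 1523 had an unadjusted p under 0.05, 1404 of them higher. After quantile normalization 712 of 1362 were higher, after median centring 779 of 1143, and without SSM replicate 3 983 of 1568. The smallest p-values after Dbp belonged to Commd6 0.21 (SE 0.044), Ndfip2 0.17 (SE 0.036), Ascc1 0.23 (SE 0.052) and Azin2 0.18 (SE 0.040) on the higher side (adjusted p = 0.649 each). On the lower side they belonged to the microtubule-binding Clasp1 -0.13 (SE 0.038), Bcl9 -0.18 (SE 0.056), the chromatin remodeller gene Chd5 -0.21 (SE 0.068), Casp6 -0.15 (SE 0.047) and Gpr139 -0.18 (SE 0.059) (adjusted p = 0.649 each). Both arrays with the highest myelin markers were morphine arrays, and Ttr was low in 3 saline arrays. Myelin genes were also raised in MSM replicate 2 (list mean 0.22, Mag 7.68), CC replicate 1 (0.20, Mag 7.32) and MSS replicate 3 (0.15, Mag 7.27), against at most -0.047 in the other 10 arrays, and the fit without 2 arrays still holds them. Without SSM replicate 1 and MSM replicate 3 the myelin median was 0.099 (adjusted p = 0.434), the glutamatergic neuron median 0.027 (adjusted p = 0.462) and the cell cycle median 0.045 (adjusted p = 0.754). In the same fit the choroid plexus median was 0.47 (adjusted p = 0.00422), the immediate early gene median -0.011 (adjusted p = 9.63e-04) and the circadian clock median 0.067 (adjusted p = 0.0189). The clock call ended with quantile normalization in addition (adjusted p = 0.0717, median 0.027), and quantile normalization alone left it at 0.0467 (median 0.049). Without the 2 arrays, and without that normalization, the synapse and vesicle release median was 0.00054 (adjusted p = 0.0189), so its call was relative to the other genes only. The calls of neurogenesis (median 0.040, adjusted p = 0.641), cholesterol synthesis (0.012, 0.163) and glutamate and GABA receptors (0.0021, 0.10) ended, with medians above 0. With arrays left out, the cell cycle call ended without SSM replicate 1 (adjusted p = 0.674, median 0.053). The cholesterol synthesis call ended without SSM replicate 1 (adjusted p = 0.0503, median -0.0094). The circadian clock call ended without MSM replicate 2 or SSM replicate 1 (adjusted p = 0.125 and 0.216, median 0.048 and 0.048). The glutamate and GABA receptors call ended without MSS replicate 1, MSM replicate 2, SSS replicate 1, SSS replicate 3 or SSM replicate 3 (adjusted p = 0.264, 0.0862, 0.180, 0.0510 and 0.3997, median 0.010, -0.0041, -0.0074, -0.042 and -0.076).

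Under mild stress alone, morphine was compared with saline through MSM and MSS. Choroid plexus genes were higher in MSM in 15 of 15, with a median of 0.83 (camera adjusted p = 5.65e-15), among them Ttr 2.69 (SE 1.02), Clic6 1.87 (SE 0.70), Kcne2 0.68 (SE 0.23) and Cldn2 0.74 (SE 0.28). Ttr was 13.10 ± 0.19 in MSM and 10.41 ± 2.30 in MSS, where the SD reflects the pair of arrays near 9. Immediate early genes, which neurons induce on activity, were lower in 15 of 18 (median -0.19, adjusted p = 2.66e-06), with Junb -0.20 (SE 0.074), Nr4a1 -0.25 (SE 0.11), Nptx2 -0.34 (SE 0.15) and Egr4 -0.20 (SE 0.092). Cell cycle genes were higher in 17 of 20 (median 0.070, adjusted p = 0.00116; Aurkb 0.28 (SE 0.089) and Ccna2 0.17 (SE 0.081)). Cholesterol synthesis genes were lower in 14 of 16 (median -0.076, adjusted p = 0.00242; the squalene synthase gene Fdft1 -0.20 (SE 0.091) and Sqle -0.16 (SE 0.086)). Myelin genes were higher in 15 of 17 (median 0.25, adjusted p = 3.61e-05; Trf 0.33 (SE 0.13) and Tspan2 0.40 (SE 0.16)). Thalamus genes were higher in 10 of 13 (median 0.32, adjusted p = 7.76e-04; Rora 0.79 (SE 0.36)). Glutamatergic neuron genes were lower in 13 of 14 (median -0.23, adjusted p = 6.69e-05; Neurod6 -0.76 (SE 0.38)). Camera with an estimated correlation gave an adjusted p of 0.830 for cholesterol synthesis and 0.646 for each of the other 6 lists. Over the list alone 6 of 15 choroid plexus genes passed and 0 in the other 6, and over all genes 0 passed. Of 19938 genes 0 passed in limma and 513 had an unadjusted p under 0.05, 316 of them higher (346 of 746 after quantile normalization, 260 of 625 after median centring). The 513 genes lay below the 997 that chance alone gives. The smallest p-values belonged to Tmem200c 0.39 (SE 0.087), Mpc1 0.23 (SE 0.060), Ndfip2 0.18 (SE 0.050), Ube2c 0.29 (SE 0.080) and Inpp5a 0.31 (SE 0.087) on the higher side. Lower in MSM were Pknox1 -0.32 (SE 0.069), Hamp2 -0.40 (SE 0.10), Tmem198 -0.29 (SE 0.077), Dnajb6 -0.38 (SE 0.11) and Fam76a -0.23 (SE 0.065) (adjusted p = 1.00 for all 10). MSM replicate 3, with its high thalamus and myelin markers, bore on 3 calls. Without it the myelin call (adjusted p = 0.111, median 0.10) and the thalamus call (adjusted p = 0.715, median 0.044) ended. So did the glutamatergic neuron call (adjusted p = 0.842, median 0.011). With SSM replicate 1 left out in addition the myelin call held (median 0.10, adjusted p = 0.0142). Without MSM replicate 3 alone the median of the immediate early genes was -0.062 (adjusted p = 0.0356). The cholesterol synthesis call ended without MSS replicate 1 or MSM replicate 2 (adjusted p = 0.0793 and 0.0606, median -0.037 and -0.057).

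Under severe stress alone, morphine was compared with saline through SSM and SSS. Dbp 0.49 (SE 0.091), Commd6 0.34 (SE 0.063) and Avpi1 0.36 (SE 0.069) had the smallest p-values on the higher side. With them stood the gasdermin gene Gsdme 0.34 (SE 0.071) and Cpn1 0.37 (SE 0.077) (adjusted p = 0.494 for each of these genes). Cpn1 was dim, at 4.12 in SSS and 4.49 in SSM. Toward lower values stood the presynaptic scaffold gene Pclo -0.41 (SE 0.11), Nav1 -0.38 (SE 0.11), the dynein heavy chain gene Dync1h1 -0.37 (SE 0.11), Myo5a -0.26 (SE 0.078) and Cep250 -0.24 (SE 0.067) (adjusted p = 0.494 each). Microglia genes were higher in 15 of 15 (median 0.17, camera adjusted p = 0.0103), with the signalling adaptor gene Tyrobp 0.20 (SE 0.066), the complement gene C1qb 0.28 (SE 0.10), Ctss 0.35 (SE 0.15) and Aif1 0.18 (SE 0.080), and myelin genes in 16 of 17 (median 0.33, adjusted p = 0.0160; Tspan2 0.41 (SE 0.16) and Trf 0.32 (SE 0.13)). Synapse and vesicle release genes were lower in 14 of 18 (median -0.026, adjusted p = 1.37e-05; Shank1 -0.33 (SE 0.10), Rims1 -0.18 (SE 0.078) and Bsn -0.25 (SE 0.12)). Glutamatergic neuron genes were lower in 9 of 14 (median -0.12, adjusted p = 0.0103; Dsp -0.24 (SE 0.12), while Calb1 0.32 (SE 0.13) went the other way). Neurogenesis genes were lower in 11 of 17 (median -0.035, adjusted p = 0.0103). Immediate early genes were lower in 11 of 18 (median -0.017, adjusted p = 0.0154). Once the correlation was estimated the adjusted p was 0.920 for myelin and 0.901 for each of the other 5 lists. Adjusted over the list alone 0 genes of these 6 lists passed, but 3 of 16 interneuron genes did (Npy 0.54 (SE 0.16), Reln -0.49 (SE 0.15) and Sst 0.31 (SE 0.10)) and 1 of 15 clock genes, Dbp, with 0 over all genes.

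In limma no gene passed between SSM and SSS (0 of 19938), and 1868 had an unadjusted p under 0.05, 1736 of them higher (810 of 1452 after quantile normalization, 861 of 1431 without SSM replicate 3). SSM replicate 1, with its high striatal and myelin markers, held the highest value of 11 of the 15 microglia genes and 8 of the 17 myelin genes. Without it the microglia call (adjusted p = 0.984, median 0.090), the myelin call (adjusted p = 0.781, median 0.080), the neurogenesis call (adjusted p = 0.445, median 0.096) and the glutamatergic neuron call (adjusted p = 0.103, median 0.044) ended, the last 2 with medians above 0 and camera's direction still lower. SS number 8 alone holds arrays of both groups, SSM replicate 1 and SSS replicate 3. Between those 2 arrays the striatal genes Scn4b (3.39) and Drd1 (3.18), chosen after their values were seen, were higher in SSM replicate 1. As each side is 1 array, the spread in that fit came from the other arrays only, and no count of genes is given. Within that pair the list medians were 0.87 for myelin, 0.23 for microglia, -0.12 for synapse and vesicle release, -0.39 for glutamatergic neuron, -0.15 for neurogenesis and -0.066 for immediate early genes. Other calls ended as follows: immediate early genes without SSS replicate 2 or SSM replicate 3 (adjusted p = 0.119 and 0.103, median 0.00059 and -0.055), myelin without SSS replicate 1 (adjusted p = 0.0879, median 0.39), glutamatergic neuron without SSM replicate 3 (adjusted p = 0.0881, median -0.19) and neurogenesis without SSS replicate 2 (adjusted p = 0.0601, median -0.011).

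The interaction contrast asked whether the difference between morphine and saline itself differed between severe and mild stress. Microglia genes had positive interaction values in 14 of 15 (median 0.15, camera adjusted p = 0.0142), with Tyrobp 0.28 (SE 0.093), C1qb 0.33 (SE 0.14), Fcer1g 0.26 (SE 0.12) and Aif1 0.25 (SE 0.11). Choroid plexus genes had negative values in 14 of 15 (median -0.61, adjusted p = 2.13e-07; Slc4a5 -0.56 (SE 0.38) and Aqp1 -0.93 (SE 0.64)). Thalamus genes had negative values in 9 of 13 (median -0.18, adjusted p = 0.0248; Lef1 -0.57 (SE 0.40)). Synapse and vesicle release genes had negative values in 10 of 18 (median -0.033, adjusted p = 0.0248; Rims1 -0.25 (SE 0.11), Shank1 -0.30 (SE 0.15) and Bsn -0.35 (SE 0.17)). With an estimated correlation the adjusted p was 0.979 for each of these 4 lists, and adjusted over the list alone, as over all genes, 0 of their genes passed. The uncalled circadian clock list had 1 of 15. The genes with the smallest p-values were the microglial receptor gene Fcrls 0.49 (SE 0.099), the leukocyte surface gene Cd48 0.49 (SE 0.10), Pknox1 0.43 (SE 0.098), Nars2 0.43 (SE 0.10) and Exo5 0.34 (SE 0.083) on the positive side (adjusted p = 0.959 each). On the negative side were the cytokine receptor gene Lifr -0.35 (SE 0.10), the myosin gene Myo19 -0.39 (SE 0.12), Itpripl1 -0.43 (SE 0.14), Acnat1 -0.32 (SE 0.11) and Tmem200c -0.37 (SE 0.12) (adjusted p = 0.959 each). No gene passed in limma (0 of 19938), and 727 had an unadjusted p under 0.05, 650 of them positive (482 of 818 after quantile normalization, 347 of 692 without SSM replicate 3). These 727 are fewer than the 997 that chance alone gives. The choroid plexus call was kept in every fit that left out 1 array, but 3 saline arrays were low in these genes, with list means of -1.02 in MSS replicate 1, -1.11 in MSS replicate 2 and -1.11 in SSS replicate 2 against -0.27 to 0.76 elsewhere. No such fit removed both MSS arrays. Microglia and thalamus genes were highest in SSM replicate 1 and MSM replicate 3 respectively. The microglia call ended without MSS replicate 2, MSM replicate 1 or SSM replicate 1 (adjusted p = 0.0631, 0.0798 and 0.833, median 0.14, 0.17 and 0.073). The thalamus call ended without MSS replicate 1, MSS replicate 2, MSM replicate 3, SSS replicate 3 or SSM replicate 3 (adjusted p = 0.0958, 0.109, 0.579, 0.0833 and 0.381, median -0.15, -0.10, 0.14, -0.057 and -0.13). That of synapse and vesicle release ended without MSS replicate 3, MSM replicate 1, MSM replicate 2, SSS replicate 1, SSM replicate 1 or SSM replicate 3 (adjusted p = 0.302, 0.286, 0.249, 0.0683, 0.0561 and 0.381, median -0.019, -0.0018, -0.014, -0.043, -0.0016 and -0.022).

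Mild stress with saline was compared with untreated controls through MSS and CC. Choroid plexus genes were lower in MSS in 15 of 15 (median -0.44, camera adjusted p = 4.48e-06), with Ttr -2.43 (SE 1.02), Clic6 -1.30 (SE 0.70) and Aqp1 -0.70 (SE 0.45), and 2 of the 3 MSS arrays had Ttr below 9.2. Cell cycle genes were lower in 16 of 20 (median -0.055, adjusted p = 0.00601; Aurkb -0.21 (SE 0.089), Rrm2 -0.20 (SE 0.091) and Top2a -0.19 (SE 0.098)). Unfolded protein and amino acid response genes were lower in 16 of 22 (median -0.088, adjusted p = 0.00714; Aldh18a1 -0.15 (SE 0.059) and Dnajb9 -0.23 (SE 0.099)). Cholesterol synthesis genes were lower in 14 of 16 (median -0.073, adjusted p = 0.0130; Hmgcs1 -0.094 (SE 0.062)). Synapse and vesicle release genes were higher in 14 of 18 (median 0.054, adjusted p = 0.0130; the adhesion gene Nlgn1 0.15 (SE 0.060)). Camera with an estimated correlation gave an adjusted p of 0.818 for each of these 5 lists, and adjusted over the list alone, as over all genes, 0 of their genes passed. In limma no gene passed (0 of 19938, smallest adjusted p = 1.00), and 442 had an unadjusted p under 0.05, 211 of them higher (165 of 710 after median centring). The 442 genes lay below the 997 that chance alone gives. The smallest p-values belonged to Dnajb6 0.49 (SE 0.11), Tmem267 0.87 (SE 0.19), Tbrg3 0.39 (SE 0.089), Sbpl 0.28 (SE 0.069) and Lce3b 0.34 (SE 0.092) on the higher side. On the lower side they belonged to Etaa1 -0.31 (SE 0.086), which acts in the replication stress response, the DNA polymerase subunit gene Pold3 -0.31 (SE 0.087) and the mitochondrial protein genes Mrpl34 -0.29 (SE 0.081), Chchd3 -0.20 (SE 0.055) and Txn2 -0.19 (SE 0.055). Without CC replicate 3 a single gene passed, Galntl6 (adjusted p = 0.00113). With arrays left out, the cell cycle call ended without CC replicate 1 or MSS replicate 1 (adjusted p = 0.0576 and 0.134, median -0.050 and -0.036). The cholesterol synthesis call ended without CC replicate 3, MSS replicate 2 or MSS replicate 3 (adjusted p = 0.339, 0.0522 and 0.179, median -0.041, -0.055 and -0.045). The unfolded protein call ended without MSS replicate 3 (adjusted p = 0.103, median -0.046). The synapse and vesicle release call ended without CC replicate 1, MSS replicate 1 or MSS replicate 2 (adjusted p = 0.152, 0.265 and 0.125, median 0.029, 0.032 and 0.043).

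Mild stress with morphine was compared with untreated controls through MSM and CC. Cholesterol synthesis genes were lower in MSM in 16 of 16 (median -0.12, camera adjusted p = 1.86e-08), with the squalene synthase gene Fdft1 -0.29 (SE 0.091), the isomerase gene Idi1 -0.20 (SE 0.087), Msmo1 -0.13 (SE 0.060) and the squalene epoxidase gene Sqle -0.19 (SE 0.086). This call held when any array was left out (adjusted p up to 9.56e-05). Thalamus genes were higher in 12 of 13 (median 0.34, adjusted p = 7.74e-06; Ptpn3 0.54 (SE 0.20) and Rora 0.89 (SE 0.36)). Myelin genes were higher in 15 of 17 (median 0.23, adjusted p = 8.46e-05; Mal 0.23 (SE 0.11) and Mag 1.23 (SE 0.61)). Choroid plexus genes were higher in 15 of 15 (median 0.34, adjusted p = 0.00151; Kcne2 0.34 (SE 0.23)). Oligodendrocyte precursor genes were higher in 12 of 14 (median 0.12, adjusted p = 0.0385; Pcdh15 0.20 (SE 0.12)). Glutamatergic neuron genes were lower in 12 of 14 (median -0.22, adjusted p = 0.00260; the calbindin gene Calb1 -0.36 (SE 0.13) and Wfs1 -0.32 (SE 0.15)). Immediate early genes were lower in 14 of 18 (median -0.11, adjusted p = 0.00917; Arc -0.19 (SE 0.10)). Neurogenesis genes were lower in 13 of 17 (median -0.10, adjusted p = 0.0316; Nes -0.34 (SE 0.097)). Unfolded protein genes were lower in 14 of 22 (median -0.057, adjusted p = 0.0499; Pdia6 -0.21 (SE 0.075)). Once the correlation was estimated the adjusted p was 0.735 for each of these 9 lists. Over the list alone 1 of 22 unfolded protein genes passed, the stress-induced Sesn2 0.34 (SE 0.077), against the list's direction. So did 1 of 19 opioid genes, Npff 0.39 (SE 0.091), which codes for neuropeptide FF, a modulator of opioid signalling. Over all genes 0 passed in limma (0 of 19938, smallest adjusted p = 1.00), and 551 had an unadjusted p under 0.05, 315 of them higher (339 of 839 after quantile normalization, 150 of 893 after median centring). Chance alone gives 997, more than these 551. The smallest p-values otherwise belonged to Agxt 0.20 (SE 0.053), Unc80 0.38 (SE 0.10) and Fam13a 0.32 (SE 0.087) on the higher side. Lower in MSM were Kbtbd7 -0.28 (SE 0.052), Rny1 -0.84 (SE 0.20), Pknox1 -0.28 (SE 0.069), Rnpep -0.31 (SE 0.080) and Clec5a -0.17 (SE 0.047). Of these, Rny1 is a small RNA and is named outside the rule. Without CC replicate 3 Galntl6 passed (adjusted p = 0.00226) and without MSM replicate 1 Rorb (adjusted p = 0.0126), each as the single gene.

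MSM replicate 3, with its high thalamus and myelin markers, bore on 6 of these 9 calls. Without it the comparison of MSM with CC lost those of thalamus (median 0.041, adjusted p = 0.399), myelin (median 0.098, adjusted p = 0.219), glutamatergic neuron (median 0.085, adjusted p = 0.450), immediate early genes (median 0.013, adjusted p = 0.919), oligodendrocyte precursor (median 0.0024, adjusted p = 0.904) and neurogenesis (median -0.016, adjusted p = 0.432). Other arrays also ended calls: CC replicate 3 those of immediate early genes (adjusted p = 0.120, median -0.11) and oligodendrocyte precursor (adjusted p = 0.690, median 0.042), and CC replicate 2 those of oligodendrocyte precursor (adjusted p = 0.238, median 0.049) and neurogenesis (adjusted p = 0.191, median -0.026). MSM replicate 2 ended that of neurogenesis (adjusted p = 0.119, median -0.19). With MSM replicate 3 and SSM replicate 1 both left out the myelin call held (median 0.098, adjusted p = 0.0360). With quantile normalization in addition the myelin call ended (adjusted p = 0.0553). The choroid plexus call ended without CC replicate 1 or MSM replicate 1 (adjusted p = 0.194 and 0.0959, median 0.20 and 0.23) and the unfolded protein call without CC replicate 1, CC replicate 2, MSM replicate 1 or MSM replicate 2 (adjusted p = 0.139, 0.141, 0.353 and 0.233, median -0.070, -0.042, -0.052 and -0.045).

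Severe stress with saline was compared with untreated controls through SSS and CC. Synapse and vesicle release genes were higher in SSS in 17 of 18 (median 0.090, camera adjusted p = 2.19e-05), with the active zone gene Bsn 0.27 (SE 0.12), the postsynaptic scaffold gene Shank1 0.22 (SE 0.10), the syntaxin gene Stx1a 0.17 (SE 0.088) and Nlgn2 0.11 (SE 0.065). Blood genes were higher in 5 of 6 (median 0.062, adjusted p = 0.0445), with the red cell anion exchanger gene Slc4a1 0.22 (SE 0.071) and the heme synthesis gene Alas2 0.50 (SE 0.21). With an estimated correlation the adjusted p was 0.883 for both lists. Adjusted over the list alone 1 of 6 blood genes and 0 of 18 synapse genes passed, and 0 over all genes. No gene passed in limma (0 of 19938, smallest adjusted p = 1.00), and 404 had an unadjusted p under 0.05, 186 of them higher (481 of 733 after quantile normalization, 455 of 617 after median centring). These 404 are fewer than the 997 that chance alone gives. The smallest p-values belonged to Ajuba 0.23 (SE 0.062), Fam169b 0.20 (SE 0.059), Galntl6 0.52 (SE 0.15) and Zfp703 0.27 (SE 0.081) and the actin-nucleating formin gene Diaph1 0.20 (SE 0.056) on the higher side. On the lower side they belonged to Etaa1 -0.37 (SE 0.086), Akap8l -0.28 (SE 0.070), Tmem87a -0.22 (SE 0.056) and Kctd18 -0.24 (SE 0.062) and the kinase subunit gene Pik3cg -0.27 (SE 0.068). Without CC replicate 3 Galntl6 passed (adjusted p = 0.00162) as the single gene. The synapse call held when any array was left out, and the blood call ended without CC replicate 1, SSS replicate 2 or SSS replicate 3 (adjusted p = 0.107, 0.0634 and 0.108, median 0.049, 0.052 and 0.072).

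Severe stress with morphine was compared with untreated controls through SSM and CC. Dbp 0.48 (SE 0.091), the carboxypeptidase gene Cpn1 0.45 (SE 0.077), Pigh 0.37 (SE 0.076) and the mitochondrial protein genes Timm8b 0.33 (SE 0.062) and Cisd1 0.29 (SE 0.061) had the smallest p-values on the higher side (adjusted p = 0.529 each). On the lower side stood Sfi1 -0.44 (SE 0.089) and Cep250 -0.28 (SE 0.067), which act at centrosomes, Med12 -0.40 (SE 0.089), the spliceosome gene Snrnp70 -0.35 (SE 0.080) and Zfp57 -0.44 (SE 0.11), a keeper of genomic imprints (adjusted p = 0.529 each). Cpn1 was dim, at 4.04 in CC and 4.49 in SSM, where Xist was 4.13 and 4.26 in these male pups. Cholesterol synthesis genes were lower in 12 of 16 (median -0.046, camera adjusted p = 8.51e-04, with Hmgcs1 -0.12 (SE 0.062) and Stard4 -0.19 (SE 0.098)). Meninges and fibroblast genes were lower in 13 of 16 (median -0.16, adjusted p = 8.51e-04; Foxc1 -0.17 (SE 0.14)). Camera with an estimated correlation gave an adjusted p of 0.941 for both lists, and adjusted over the list alone 0 of their genes passed. Of the clock genes 3 of 15 passed adjusted over the list alone, Dbp and the nuclear receptor genes Nr1d1 0.29 (SE 0.079) and Nr1d2 0.27 (SE 0.084), and 0 over all genes. Camera did not call the clock list (adjusted p = 0.114), and the mixed form of fry did (adjusted p = 0.00653). In limma no gene passed (0 of 19938), and 1796 had an unadjusted p under 0.05, 1581 of them higher (961 of 1497 after quantile normalization, 626 of 1186 without SSM replicate 3). Without CC replicate 3 Galntl6 passed (adjusted p = 4.30e-04) as the single gene. The cholesterol synthesis call ended without CC replicate 3 or SSM replicate 1 (adjusted p = 0.0598 and 0.0863, median -0.016 and 0.0083) and the meninges call without CC replicate 2 or SSM replicate 1 (adjusted p = 0.249 and 0.599, median -0.030 and 0.14). Without SSM replicate 1 both medians were above 0, while camera's direction stayed lower.

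An F-test asked whether a gene differed anywhere among the 5 groups. None of 19938 genes passed in limma (0, smallest adjusted p = 0.166), and 1444 had an unadjusted p under 0.05. Comparisons against CC share the 3 CC arrays, which alone make their differences correlate across genes, and 3 arrays are too few to divide. The differences of MSS and SSS from CC correlated across genes at 0.474, against 0.516 simulated for unchanged groups with the same shared arrays, with covariances of 0.00352 and 0.00399. For MSM and SSM against CC the correlation was 0.193 against 0.305 simulated (covariances 0.00194 and 0.00399), and for MSS and SSM 0.0140 against 0.383 (covariances 1.20e-04 and 0.00400). It was 0.309 against 0.412 for MSS and MSM, 0.174 against 0.410 for MSM and SSS, and 0.305 against 0.381 for SSS and SSM, so all 6 pairs lay below the simulated value. The differences of MSM from MSS and of SSM from SSS, which share no array, correlated at 0.315 against a simulated 0.000245 (covariances 0.00383 and 2.56e-06). Those of SSS from MSS and of SSM from MSM correlated at 0.326 against a simulated -0.000407 (covariances 0.00367 and -5.43e-06). Both of these severity differences also carry a difference between SS numbers, which the simulation left out. For the morphine differences it left out that arrays standing apart lie on the same side of both. Ttr was low in saline arrays of both stress levels, and MSM replicate 3 and SSM replicate 1 held the highest myelin markers. A shared morphine response cannot be told apart from this. The simulated genes were also drawn independently, whereas measured genes can move together. Genes are not independent replicates, so no p-value is given for these values, and no gene passed in both comparisons of any pair.

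The remaining 13 lists were not called in any comparison. Those closest to the treatment included glucocorticoid response genes (23 measured), whose smallest adjusted p was 0.148 in MSM against CC (median 0.041; Lcn2 0.19 (SE 0.086), Dusp1 -0.25 (SE 0.11) and Sgk1 0.16 (SE 0.079)). Corticotropin and steroid receptor genes followed (0.333, SSM against MSM, median 0.12; Fkbp4 0.16 (SE 0.060)). Fkbp5, a classical glucocorticoid target, was 7.72 ± 0.063 in CC, 7.65 ± 0.10 in MSS, 7.73 ± 0.061 in MSM, 7.79 ± 0.087 in SSS and 7.80 ± 0.053 in SSM. Opioid peptide, receptor and signalling genes had a smallest adjusted p of 0.561 in MSM against MSS (median 0.085; Oprl1 0.19 (SE 0.13)). The morphine receptor gene Oprm1 was 4.91 ± 0.13 in CC, 4.91 ± 0.045 in MSS, 4.87 ± 0.031 in MSM, 4.80 ± 0.044 in SSS and 5.02 ± 0.10 in SSM, and it and Fkbp5 are named outside the rule. The smallest adjusted p was 0.149 for hypoxia response (morphine averaged, median 0.072), 0.149 for heat shock (MSS against CC, median -0.054), 0.160 for fatty acid oxidation (morphine averaged, median 0.072) and 0.397 for dopamine, serotonin, noradrenaline and acetylcholine genes (MSS against CC, median -0.062). For inflammation and acute phase (median 0.00043) and interferon response genes (median -0.033) it was 0.541, in both cases for SSS against MSS, and for apoptosis genes 0.261 (SSM against CC, median 0.026). Among cell types it was 0.106 for endothelium and pericytes (morphine averaged, median -0.0081), 0.108 for ependyma and cilia (morphine averaged, median 0.12) and 0.109 for interneurons (SSM against SSS, median 0.24).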

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

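The striatum list, the further thalamus genes, their tests and the list fits without single arrays were chosen only after the results were seen. The morphine difference under severe stress departed from that under mild stress, by the test of the interaction itself, in 4 gene lists, none of which held with an estimated correlation (adjusted p = 0.979 each). The median interaction was 0.15 for microglia, -0.033 for synapse and vesicle release, -0.61 for choroid plexus and -0.18 for thalamus. The choroid plexus call was kept when any 1 array was left out (adjusted p up to 0.0374, median -0.23 without SSS replicate 3), but the genes were low in MSS replicates 1 and 2 and SSS replicate 2 (Ttr 9.17, 8.99 and 8.87), and no such fit removed both MSS arrays. The microglia call ended without MSS replicate 2, MSM replicate 1 or SSM replicate 1 (median 0.14, 0.17 and 0.073), and the thalamus median was 0.14 without MSM replicate 3.

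SSM replicate 1 stood apart from the other arrays, and its microglia, myelin and striatal genes were high together. A group effect of morphine under severe stress as the whole of it is argued against by the other 2 SSM arrays. They lay lower by 0.67 in the mean of the striatum list. At -0.051 and 0.035 both lay above every SSS array (highest -0.072). These means were not rescaled, and 1 of the 2 arrays is SSM replicate 3, whose genes lay higher by a median of 0.16. A small group difference is therefore neither shown nor excluded. RNA of striatum in that array is a candidate source: the list mean was 0.67, higher by 0.43 than the next array (CC replicate 1 at 0.24, SD of the other 14 arrays 0.11), and 13 of 16 members peaked there. Penk was 11.40, Ppp1r1b 10.32 and Drd1 9.72 in that array, and hippocampus also expresses some of these genes. No test told striatal tissue from white matter next to it, which stays open for the myelin genes.

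MSM replicate 3 was picked for its thalamus genes (11 of 13 list members peaked there, with a list mean of 1.05 against at most 0.16 elsewhere), which carried the negative thalamus interaction. In 9 further thalamus genes, none of them in that list or among those that had drawn attention, a group effect of morphine under mild stress is argued against by the other 2 MSM arrays, which lay lower by 0.64 and, at -0.024 and -0.0084, within the range of MSS (-0.089 to 0.041). RNA of thalamus in that array is a candidate source: the mean of these 9 genes was 0.63, higher by 0.58 than the next array (MSS replicate 3, SD of the other 14 arrays 0.051), and 6 of 9 peaked there. Tcf7l2 was 9.85, Slc17a6 10.99 and Rora 8.45 in that array, whereas Prkcd, also a thalamus gene, was 7.42 there, the lowest of the 15 arrays. Which part of the thalamus this would be was not tested.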

How the results depend on the processing

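The fits without SSM replicate 1 and MSM replicate 3 and the list medians under scaling and left-out arrays were chosen after the results were seen. The count of 0 genes in limma held under every alternative fixed beforehand, except as follows, for the comparisons with CC, both morphine differences, SSS against MSS, SSM against MSM, the interaction, the averaged morphine contrast and the F-test, and the cause was not tested. Over the fits that left out an array the counts ranged from 0 to 1 in each comparison with CC, in MSM against MSS, in SSM against MSM and in the F-test, and from 1 to 17 in the severity contrast. The array was CC replicate 3 for every comparison with CC (Galntl6), MSM replicate 1 for the 3 pairs that include MSM (Rorb), and for the F-test CC replicate 2 (Mir380), CC replicate 3 (Galntl6) or MSM replicate 3 (Mir99a). The severity count of 2 became 17 without SSS replicate 3, 5 without SSM replicate 3 and 3 without SSS replicate 2. It was 18 with trend and robust variance, 67 over every probe set, 14 after quantile normalization, 32 after median centring, 43 with array weights, 1 with the SS number as a random block (consensus correlation 0.0650). It was 0 without the 40% dimmest genes, a filter that removed Mir380 and left Kbtbd7 at an adjusted p of 0.0515 (0.00974 to 0.172 over all alternatives). Over every probe set 2 passed in SSM against MSM and 1 in the F-test. With the SS number as a fixed block SSM against SSS compares SSM replicate 1 with SSS replicate 3 alone. There the count did not stay at 0, but each side is 1 array, so no count is given. Without SSM replicate 1 and MSM replicate 3, 1 gene passed in SSS against MSS and 1 in the F-test (Mir99a in both). In that fit 2 passed in the severity contrast, Mir380 and Mir99a, and Kbtbd7 did not. With quantile normalization in addition 1 passed there (Mir99a), and neither Mir380 nor Kbtbd7 did. MSM and CC share the numbers H1 to H3, given only in the titles. As a replicate block they left 0 genes past the threshold (391 at an unadjusted p under 0.05 against 551). The deviations of equal numbers correlated at -0.39, -0.069 and -0.16. With so few pairs, and MSM replicate 3 apart from the other MSM arrays, this cannot exclude that equal numbers mark a shared source.

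Of the 54 list calls 0 held with an estimated correlation and 0 with fry, and the cause was not tested. There were 42 list calls after quantile normalization, 38 of them among the 54, and the other 16 ended with medians of unchanged sign. By adjusted p these were cholesterol synthesis (0.149) and unfolded protein (0.0848) in MSS against CC, and oligodendrocyte precursor (0.0517), neurogenesis (0.119) and unfolded protein (0.141) in MSM against CC. They were blood in SSS against CC (0.0567), meninges in SSM against CC (0.162), oligodendrocyte precursor in SSM against MSM (0.105), and immediate early genes (0.123), glutamatergic neuron (0.161) and neurogenesis (0.123) in SSM against SSS. The last were synapse and vesicle release (0.142) and thalamus (0.307) in the interaction, glutamate and GABA receptors in the averaged morphine contrast (0.111), and myelin (0.0660) and unfolded protein (0.0889) in the severity contrast. Some medians moved over 1.5 times with that normalization. In SSM against SSS they were -0.080 against -0.026 for synapse and vesicle release, -0.058 against -0.017 for immediate early genes and -0.064 against -0.035 for neurogenesis. They were -0.11 against -0.046 for cholesterol synthesis in SSM against CC, -0.13 against -0.076 for oligodendrocyte precursor in SSM against MSM and -0.073 against -0.033 for synapse and vesicle release in the interaction. In the averaged morphine contrast they were -0.063 against -0.031 for glutamate and GABA receptors, -0.071 against -0.035 for cholesterol synthesis and -0.096 against -0.062 for synapse and vesicle release, and 0.049 against 0.080 for the circadian clock. Leaving out an array gave 51 to 74 list calls. Of the 14 calls kept in each of these fits, 7 had a median over 1.5 times smaller or larger in the fit with the largest p. These were choroid plexus in MSS against CC (-0.27 without MSS replicate 2) and the interaction (-0.23 without SSS replicate 3), immediate early genes in MSM against MSS (-0.062 without MSM replicate 3), and synapse and vesicle release in SSM against SSS (-0.043 without SSM replicate 3). The others were immediate early genes (-0.046 without MSM replicate 3), myelin (0.16 without SSM replicate 1) and glutamatergic neuron (-0.073 without MSM replicate 3) in the averaged morphine contrast. Without SSM replicate 1 and MSM replicate 3 (in brackets with quantile normalization in addition) some medians changed sign. In MSM against CC this was so for immediate early genes 0.013 (0.011) and glutamatergic neuron 0.085 (0.091), in MSM against MSS for glutamatergic neuron 0.011 and in SSM against MSM for thalamus 0.018. In SSM against CC it was so for cholesterol synthesis 0.0083 and meninges 0.14 (0.096), and in SSM against SSS for immediate early genes 0.019, glutamatergic neuron 0.044 and neurogenesis 0.096 (0.028). In the interaction the thalamus median was 0.078 (0.025). In the averaged morphine contrast the medians were 0.027 for glutamatergic neuron, 0.040 (0.0026) for neurogenesis, 0.012 for cholesterol synthesis, 0.0021 for glutamate and GABA receptors and 0.00054 for synapse and vesicle release. With quantile normalization in addition the oligodendrocyte precursor median in MSM against CC (-0.0029) and the microglia median in the interaction (-0.0028) changed sign too. Direction against the other genes, but not sign, changed for oligodendrocyte precursor in MSM against CC (0.0024), thalamus in MSM against MSS 0.044 (0.030), and myelin (0.080) and microglia 0.090 (0.022) in SSM against SSS. Over the fits that left out a single array, immediate early genes in MSM against CC ranged from -0.20 to 0.013, oligodendrocyte precursor from 0.0024 to 0.22 and glutamatergic neuron from -0.38 to 0.085. Thalamus ranged from 0.044 to 0.47 in MSM against MSS and from -0.34 to 0.14 in the interaction, and each of these 5 changes came without MSM replicate 3. In SSM against SSS myelin ranged from 0.080 to 0.49 and microglia from 0.090 to 0.24, with the lowest value of both without SSM replicate 1. These arrays carry the neighbouring-tissue markers, and for the other changes the cause was not tested.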

Other observations

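The list of RNAs known to be retained in the nucleus was made, and its tests chosen, only after the severity result was seen. Its 14 measured genes, among them the splicing kinase gene Clk4 (-0.45, SE 0.082), Rsrp1 (-0.42, SE 0.083), Wsb1 (-0.40, SE 0.10), Luc7l3 (-0.37, SE 0.080) and Son (-0.25, SE 0.047), were all lower under severe than under mild stress, 14 of 14 with a median of -0.26. Over the list alone 12 passed and over all genes 0, and after quantile normalization the median was -0.30, with 14 past the threshold adjusted over the list alone and 2 over all genes. Camera gave this list an adjusted p of 5.36e-27 with the preset and 0.00561 with an estimated correlation, and fry 0.00199. These p-values, as those below, are adjusted over the 2 lists added afterwards, not over the 30 fixed beforehand, so they cannot be compared with those of the 30. The list was also made because such genes led the severity contrast, so they do not count as a test. All 14 genes were also lower in SSM than in CC (median -0.21, adjusted p = 0.0101 with an estimated correlation), in SSS than in MSS (-0.21, 0.0155) and in SSM than in MSM (-0.30, 0.0134). All 14 were lower in SSS than in CC as well (-0.21, 0.0394), but 0 of 14 passed adjusted over the list alone and fry gave an adjusted p of 0.0821. In MSM against MSS 8 of 14 were lower (median -0.0076) and in SSM against SSS 10 of 14 (median -0.047, after quantile normalization -0.098), there with an adjusted p of 0.00120 with the preset and 0.326 with an estimated correlation.

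Per array the mean of this list, after quantile normalization, was 0.13 ± 0.048 (SD, n = 6) under mild stress, -0.17 ± 0.12 (n = 6) under severe stress and 0.069 ± 0.11 (n = 3) in CC. All 6 mild-stress arrays lay above every severe-stress array. SSS replicate 1 (-0.32) lay below SSS replicates 2 and 3 (-0.062 and 0.011), of which only replicate 3 fell within the range of CC (-0.034 to 0.18). A stress-level difference in nuclear-retained RNA is a hypothesis that these values allow (two-sided exact permutation p = 0.00216 for 6 against 6, on a list made after the pattern was seen). A trend with gene length between arrays is argued against: removing it left 109% of the median, and the fold changes of the severity contrast correlated with gene length at -0.050 after quantile normalization and -0.0063 as deposited (Spearman, across genes). The SS number cannot be told apart from the stress level, since it is nested in it, and over the 3 SS numbers of severe stress the list mean ranged over 0.14. A difference in how the RNA was extracted between batches may give the same picture, and neither this nor the nuclear share of the RNA was measured.

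Other splits of the same arrays were counted by genes with an unadjusted p under 0.05, as planned. For the severity contrast chance is excluded only as far as the arrays can be exchanged for one another: 1 of 100 splits, the real one, gave as many (2410, highest other 2068). All mild-stress arrays share SS number 11 and the severe-stress arrays have 8 to 10, so a grouping by SS number stays open, and with it as a random block the count was 1692. Chance is not excluded for the averaged morphine contrast (6 of 100, 1523 against 1846) or the F-test (6 of 100, 1444 against 1769). For the interaction 80 of 100 gave as many (727 against 2433). Its splits moved labels freely over all stressed arrays, so a split can line up with the severity contrast (2410). These splits therefore cannot decide about chance for the interaction. For 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real counts and the highest others were 442 and 1089 for MSS against CC (4 of 10 as large), 551 and 1623 for MSM against CC (8), 404 and 842 for SSS against CC (5), and 1796 and 1959 for SSM against CC (3). They were 513 and 966 for MSM against MSS (9), 1868 and 1866 for SSM against SSS (1), 568 and 884 for SSS against MSS (4), and 2858 and 2600 for SSM against MSM (1). The highest other splits of MSS, MSM and SSS against CC were over 2 times the real counts, which lay below the 997 genes that chance alone gives. For SSS against CC the highest split (842) lay below 997 too. These ratios therefore do not show a structure of the samples, and their cause was not tested.

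Of the striatum list, 15 of 16 genes were higher in SSM than in SSS (median 0.36, adjusted p = 0.326 with an estimated correlation) and 0 of 16 were higher in SSS than in CC (median -0.057, adjusted p = 0.456). CC replicate 1 stood out in the second, with a list mean of 0.24 against -0.14 and -0.071 in the other CC arrays and -0.11 to -0.072 in SSS. SSM replicate 1 stood out in the first, with a list mean of 0.67 against -0.0078 in the other 2 SSM arrays.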
